A study of Mus musculus with 18 samples.

How the data were processed

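RNA was measured in NIH3T3 mouse fibroblasts after 2 h of 100 nM dexamethasone and a medium change (0 h). Cells were harvested every 4 h from 0 h to 32 h, with 2 libraries at each of 9 time points. The deposited table holds 1 signal value per gene and library, which the authors had made as read counts per gene divided by 1 factor per library and rounded to 2 decimals. The labels name TopHat, HTSeq, DESeq and the mouse genome build mm9, without versions, roles or an annotation. The libraries are not pooled. Dividing each column by its step gave whole reads within 0.02 reads for every value (largest distance 0.0104). The factors, from 0.728 to 1.16, differed by at most 1.08e-06% from DESeq's median-of-ratios size factors computed here. The libraries held 25.4 to 38.9 M reads, their normalized totals were 30.0 to 35.1 M, and the 10 genes with the most reads took 5.70% to 8.09% of a library. Because the reference at hand was a later genome build, no coordinates are given.

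Genes with a mean of at least 10 normalized reads (12393 of 21937) were tested with limma 3.58.1 in R 4.3.3. The fits used log2(value + 1), a variance trend, all 18 libraries and a Benjamini-Hochberg threshold of 0.05. A moderated F over the 9 time points was followed by contrasts of each time with 0 h, of 28 h with 4 h and of 32 h with 8 h. A rhythm was tested by a moderated F of a cosine and a sine with a period of 24 h, and a linear drift by the coefficient of time beside them. The design, the gene lists, the rule for naming genes and the alternatives, apart from those described as chosen later, were fixed before the data were examined. Set tests took lists with at least 3 tested members, 24 tests per contrast. Camera was run with an inter-gene correlation preset at 0.01 and with an estimated one, and fry beside it. Fry asks if a list moves on balance in 1 direction, without a comparison with other genes. A small list can therefore pass it through 1 strongly changed gene, so its p is not an alternative to that of camera. For the rhythm, the members past the threshold were compared with all other tested genes by a one-sided Fisher's exact test. Camera, fry and the limma tests were 2-sided.

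The 26 lists held 434 genes in 435 memberships, of which 418 genes were in the table. They cover clock genes driven through E-boxes or D-boxes, clock genes driven through REV-ERB/ROR elements, other clock components, glucocorticoid receptor targets, immediate early genes, SRF and MRTF cytoskeletal targets, DNA replication (G1/S) genes, mitosis (G2/M) genes, sterol synthesis genes, extracellular matrix genes, the ATF4 amino acid response, endoplasmic reticulum chaperones, heat shock proteins, NF-kB and cytokine genes, interferon-stimulated genes, hypoxia and glycolysis genes, cytosolic ribosomal proteins, ribosome biogenesis genes, replication-dependent histones, and epithelial, leukocyte, endothelial, adipocyte, skeletal muscle and neural markers. Mitochondrially encoded transcripts, the last list, and Noc2l are not in the table and were not analysed here. Named genes were the measured clock list members, the 12 passing genes with the largest fitted peak-to-trough fold (mean of at least 50, peak hours of the replicates within 3 h), the 8 highest and 8 lowest passing genes of 4 contrasts with both libraries beyond the other time's, the 5 steepest drifts each way, and up to 4 members of each list with the smallest p. Some of these genes are not reported here.

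Alternatives were other pseudocounts and filters, equal totals or quantile normalization, eBayes without a trend or robust, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, a replicate block, leaving out each library, each replicate alone for the rhythm, other periods, a linear term, leaving out early times, and a minimum fold. A time point left with 1 library was assumed to vary like the others. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The fits were tested on simulated data for 12360 genes, with 50 genes changed by each of 4 folds. Of the genes changed 2.0-fold, limma found 92.0% at 4 h against 0 h, with 15 calls among unchanged genes, and 80.0% in the rhythm test, with 4. The simulated replicates did not differ, few simulated genes drifted, and the rhythmic ones did not. The real libraries differ in these points, so the shares are not those of the real data. The replicate numbers pair the libraries: the deviations of same-numbered libraries from their time point's mean were correlated above 0.1 in all 36 pairs of time points (0.230 to 0.502, median 0.345). The labels state no source of this pairing. The main fits leave it out, so differences between the replicates widen their spread. A replicate block is an alternative, with which more genes passed at 4 h against 0 h and at 32 h against 8 h, as given below.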

Results

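NIH3T3 cells, a line of mouse embryo fibroblasts, had been given a pulse of 100 nM dexamethasone, a synthetic glucocorticoid that sets the phase of the circadian clocks in a culture, for 2 h. The medium change that ended the pulse was 0 h. RNA was sequenced at 9 times from 0 h to 32 h, 4 h apart, with 2 libraries at each time (replicate 1 and replicate 2), 18 libraries in all. No library came from untreated cells, so each change below is measured from another time of the same series. The libraries held 25.4 to 38.9 M reads in genes, 31.9 to 38.9 M in replicate 1 and 25.4 to 32.0 M in replicate 2. Of 21937 genes in the table, 4267 were at 0 in all libraries and 12393 had a mean of at least 10 normalized reads and were tested. Levels are normalized reads as mean ± SD (n = 2). Log2 changes are given ± SE on the log2(value + 1) scale, which understates the change of low genes. Every adjusted p is from limma, or from camera for a list, unless another test is named. The labels do not say whether replicate 1 and replicate 2 were separate cultures. The p-values of the contrasts and of the F test over the 9 times therefore measure only the spread between these libraries. In the rhythm and drift fits the p-values and SE also take in changes over time that the fitted curve does not describe. Genes are named by the symbols in the table, which gives no other identifier.

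The number of genes that differed from 0 h was lowest at 4 h and highest at 32 h. Kcnj2, an inward rectifier potassium channel, rose from 36.6 ± 7.04 at 0 h to 457 ± 8.19 at 32 h. The moderated F test found that 6439 of the 12393 genes (52.0%) differed among the 9 times. Compared with 0 h, the number of genes past the threshold was 2664 at 4 h, 4263 at 8 h, 4489 at 12 h, 4520 at 16 h, 4778 at 20 h, 4611 at 24 h, 4930 at 28 h and 5059 at 32 h. Changes of at least 2-fold were more often falls: at 32 h 412 genes were lower and 243 higher by that much, and at 8 h 273 lower and 83 higher. The count at 8 h was 2571 without 0 h replicate 2. The deposited scaling put the share of higher genes at 50.3% at 8 h, 49.9% at 12 h, 51.2% at 16 h, 50.7% at 20 h, 49.8% at 28 h and 50.1% at 32 h. With the libraries rescaled to the same total these shares were 77.7%, 80.1%, 80.4%, 80.1%, 81.3% and 81.0%. That rescaling moved the median of all genes from 0 h by 0.14 log2 at 8 h, 0.18 at 12 h, 0.19 at 16 h, 0.20 at 20 h, 0.21 at 24 h, 0.22 at 28 h and 0.22 at 32 h, so directions of small changes hold only relative to the deposited scaling.

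**Figure D1:**
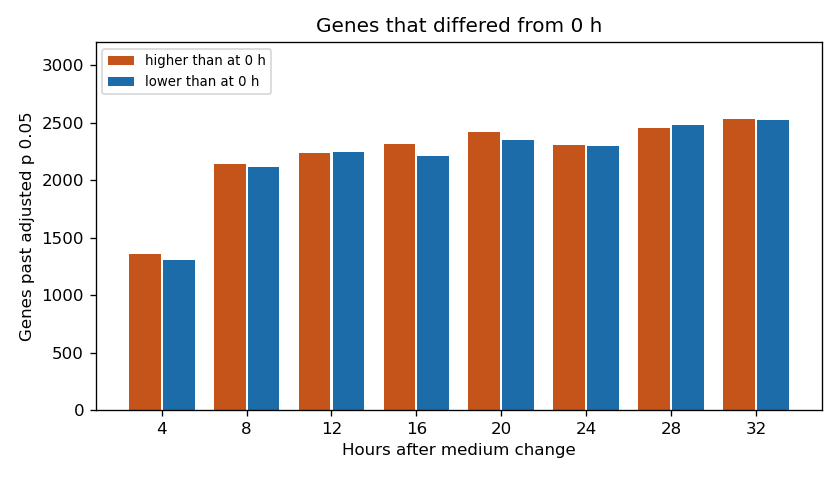
Number of genes (vertical axis) past an adjusted p of 0.05 at each time against 0 h (horizontal axis, hours after the medium change), with bars for genes that were higher and lower. The bars hold 1361 higher and 1303 lower genes at 4 h and 2536 higher and 2523 lower genes at 32 h.

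Which genes cycled with a period of 24 h was asked by fitting a cosine and a sine to all 18 libraries. Nr1d1 and Nr1d2, which encode the repressors REV-ERB alpha and beta, peaked at 21.7 ± 0.425 h (SE) and 22.2 ± 0.196 h after the medium change, with fitted peak-to-trough folds of 3.34 and 5.25 (adjusted p = 0.000175 and 3.93e-09). The period genes, whose proteins inhibit CLOCK and BMAL1, had these fitted peaks: Per1 at 0.239 ± 0.633 h (2.15-fold, adjusted p = 0.0202), Per3 at 0.566 ± 0.337 h (5.58-fold, adjusted p = 1.44e-05) and Per2 at 2.32 ± 0.245 h (12.5-fold, adjusted p = 3.51e-07). The cryptochrome partners of the period proteins peaked as follows: Cry2 at 2.93 ± 0.338 h (3.11-fold) and Cry1 at 4.65 ± 0.32 h (4.79-fold). Arntl, which encodes BMAL1, peaked at 11.4 ± 0.584 h with a fold of 1.69 (adjusted p = 0.00918). Per2 levels were 2252 ± 646 at 0 h, 173 ± 11.7 at 12 h and 1567 ± 134 at 24 h, while Arntl was at 592 ± 39.8 at 24 h and 1180.3 ± 45.6 at 32 h. Clock, the partner of BMAL1, had a fold of 1.09 and did not pass (adjusted p = 0.298).

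**Figure D2:**
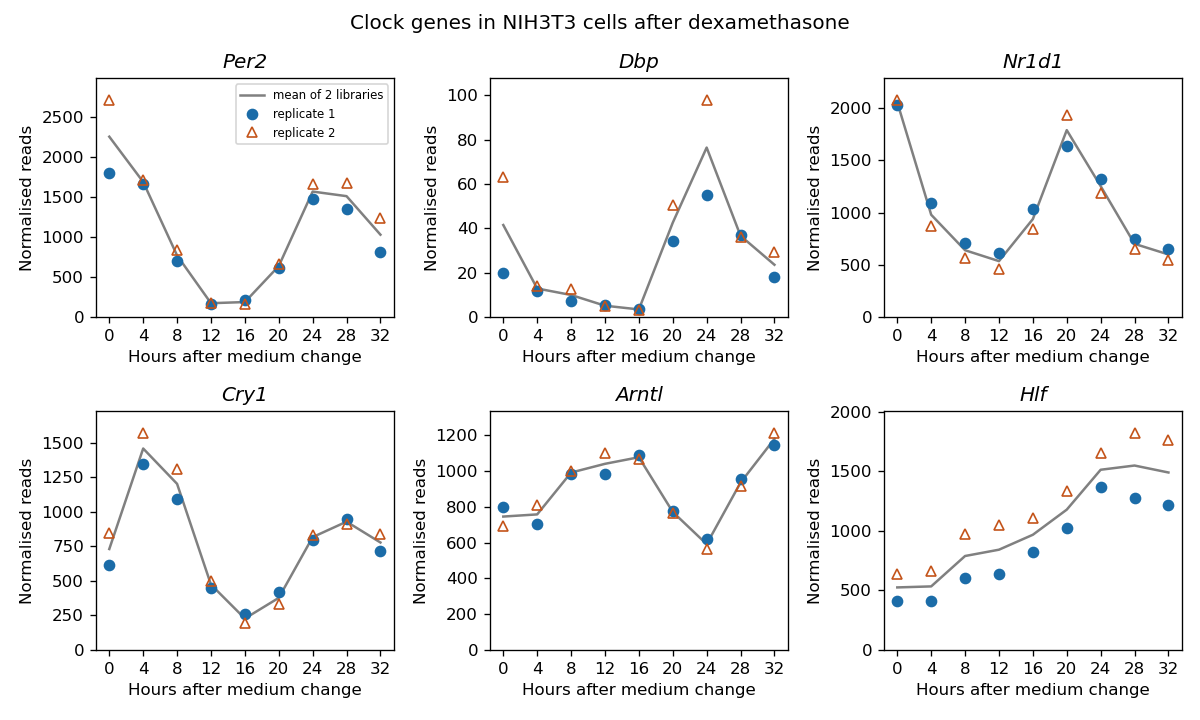
Normalized reads of 6 clock genes (vertical axis) against hours after the medium change (horizontal axis), with a point for each library and a line through the mean of the 2 libraries. Per2 is lowest at 12 h and 16 h, Nr1d1 and Dbp rise again by 20 h and 24 h, Cry1 follows them, Arntl is lowest at 24 h, and Hlf climbs from 0 h to 28 h.

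Of the 14 tested clock genes driven through E-boxes or D-boxes, 9 passed the rhythm test (13 adjusted over the list alone), against 46 of all tested genes (one-sided Fisher's exact test, adjusted p = 2.76e-18). Besides the genes above, these were Tef and Dbp, transcription factors of the PAR bZIP family (3.88-fold and 8.56-fold), Ciart, listed as Gm129, a repressor of the clock (4.02-fold), and Wee1, a kinase that holds back mitosis (1.48-fold). Hlf, the remaining PAR bZIP factor, did not pass: its level was 526 ± 156 at 0 h, 967 ± 201 at 16 h and 1548 ± 385 at 28 h. Bhlhe40 and Bhlhe41, repressors at E-boxes, had folds of 3.75 and 2.9 (adjusted p = 0.149 and 0.116). Usp2 did not pass either (adjusted p = 0.152). Among clock genes driven through REV-ERB/ROR elements, Cry1, Arntl and E2f8, a repressor of cell cycle genes that peaked at 15.3 ± 0.622 h, made 3 of 5 that passed (Fisher's exact test, adjusted p = 5.71e-06), and Clock and Nfil3 did not. That list did not pass with replicate 1 alone or with replicate 2 alone (adjusted p = 1 in both, alternatives from 7.05e-07 to 1). E2f8 (1.27-fold) peaked nearer to Ccne1 of the DNA replication (G1/S) list (15.1 h) than to Arntl (11.4 h). Which elements drive E2f8 here was not tested. Of the 10 other clock components 1, Cry2, passed (Fisher's exact test, adjusted p = 0.292). Csnk1d, Csnk1e, Btrc, Timeless, Gsk3b, Nono, Wdr5 and Fbxw11 did not (adjusted p from 0.309 to 0.974).

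Outside the clock lists, the largest fitted folds by the naming rule were those of Plekha4 (2.37-fold, peak at 3.47 ± 0.599 h), Eif5a2, a form of the translation factor eIF5A (1.88-fold, 4.44 ± 0.667 h), Pmvk, a kinase of the mevalonate pathway (1.86-fold, 4.24 ± 0.469 h) and Ier5l (1.84-fold, 0.0638 ± 0.439 h). The 46 genes fell into 16 that peaked from 0 h to 4 h, 6 from 4 h to 8 h, 4 from 8 h to 12 h, 11 from 12 h to 16 h, 3 from 16 h to 20 h and 6 from 20 h to 24 h. Of the 25 DNA replication (G1/S) genes, 1 passed over all genes, Ccne1, which encodes cyclin E1 (1.35-fold, peak at 15.1 ± 0.676 h), and 20 passed adjusted over the list alone (Fisher's exact test over all genes, adjusted p = 0.427). That list passed Fisher's exact test in 12 of 43 alternatives, among them without 0 h replicate 2, without 24 h replicate 1 and without 28 h replicate 1 (adjusted p = 0.000546, 0.0174 and 0.0333), with DESeq2 (2.16e-09) and with a linear term in time (1.55e-16, alternatives from 1.55e-16 to 1). Sterol synthesis genes passed by limma in 0 of 18 cases over all genes and in 11 adjusted over the list alone, and 12 had an unadjusted p under 0.05. By edgeR 0 passed and by DESeq2 7. Nsdhl and Lss peaked at 3.99 ± 0.711 h and 3.82 ± 0.763 h (adjusted p = 0.067 and 0.0764). Nsdhl passed with a replicate block and without 28 h replicate 1 (adjusted p = 0.0309 and 0.0253, alternatives from 0.00127 to 0.946). Of 21 tested glucocorticoid receptor targets 1 passed, Per1, and 4 passed adjusted over the list alone (Fisher's exact test, adjusted p = 0.427, and 0.0164 without 24 h replicate 1, alternatives from 0.00958 to 1). In 20 lists no member passed by limma, and 52 of their genes had an unadjusted p under 0.05, with 0 passing by edgeR and 21 by DESeq2. Of those lists only the sterol list, heat shock proteins (1) and NF-kB and cytokine genes (1) had members that passed adjusted over the list alone. Several of the 20 lists passed Fisher's exact test in an alternative. With a linear term these were mitosis (G2/M) genes, endoplasmic reticulum chaperones, and sterol synthesis, extracellular matrix, and hypoxia and glycolysis genes (adjusted p = 6.67e-05, 1.67e-08, 0.000159, 0.0166 and 0.0293). With DESeq2 they were sterol synthesis and immediate early genes (5.82e-05 and 0.0438), and without 0 h and 4 h mitosis genes (5.53e-11). A period of 26 h gave the sterol and chaperone lists (4.90e-05 and 0.0436), and 28 h gave these and cytosolic ribosomal proteins (3.33e-06, 8.21e-11 and 6.78e-07). Without 0 h, 4 h and 8 h the mitosis, chaperone, sterol, SRF and MRTF, matrix, heat shock and muscle lists passed (6.38e-16, 2.09e-12, 0.00224, 0.00555, 0.0217, 0.0409 and 0.0484). The times left then span less than 24 h, so a drift can be fitted there as part of a cycle. All alternatives of these lists ran from 3.84e-21 to 1.

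The count of 46 was 2107 at an unadjusted p under 0.05, 74 with a replicate block and 2108 with a linear term in time beside the cosine and sine. Leaving out a library gave 18 without 12 h replicate 1, 19 without 12 h replicate 2, 21 without 16 h replicate 1 and 21 without 16 h replicate 2, 22 without 20 h replicate 1, 24 without 8 h replicate 1 and 24 without 8 h replicate 2, 26 without 4 h replicate 1, 30 without 0 h replicate 1 and 30 without 28 h replicate 2. Replicate 1 alone gave 2 genes, Per2 and Nr1d2, and replicate 2 alone gave 1, Nr1d2, the only named gene whose call held in every alternative run. Leaving out a single library ended the calls of 8 of the other named genes. Per1 did not pass without either library of 12 h or 16 h (adjusted p from 0.0528 to 0.0846, all alternatives from 6.23e-06 to 0.946). Ciart did not pass without 12 h replicate 2 (adjusted p = 0.0525, all alternatives from 8.52e-07 to 0.946). Wee1 did not pass without 12 h replicate 1 (adjusted p = 0.0519, all alternatives from 6.33e-07 to 0.946). E2f8 did not pass without either library of 8 h, 12 h or 16 h, 0 h replicate 1, 20 h replicate 1 or 28 h replicate 2 (adjusted p from 0.0502 to 0.131, all alternatives from 3.4e-05 to 0.946). Dbp did not pass without either library of 8 h, 12 h, 16 h, 20 h, 24 h or 28 h, 0 h replicate 2 or 32 h replicate 1 (adjusted p from 0.0501 to 0.122, all alternatives from 0.000209 to 0.946). Plekha4 did not pass without either library of 12 h or 16 h, 4 h replicate 2, 20 h replicate 1 or 28 h replicate 2 (adjusted p from 0.0506 to 0.10, all alternatives from 0.000145 to 0.946). Eif5a2 did not pass without either library of 4 h, 8 h, 16 h, 20 h or 24 h, 0 h replicate 1, 12 h replicate 1, 28 h replicate 2 or 32 h replicate 2 (adjusted p from 0.0511 to 0.166, all alternatives from 0.000632 to 0.946). Ccne1 did not pass without either library of 4 h, 8 h, 12 h, 16 h or 20 h, 0 h replicate 1, 24 h replicate 2, 28 h replicate 2 or 32 h replicate 1 (adjusted p from 0.0521 to 0.156, all alternatives from 0.000513 to 0.946).

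The comparison of 4 h with 0 h asked what changed in the hours just after the pulse and the medium change. Immediate early genes, transcription factors and signal dampers that respond within minutes to growth factors, fell: Egr3 was 9.97-fold lower at 4 h (log2 -3.32 ± 0.34, adjusted p = 2.01e-05), Egr1 5.0-fold lower, Junb 4.42-fold lower, Fosb 4.13-fold lower and Egr2 3.83-fold lower. Egr2 went from 3700.4 ± 856 to 952 ± 37 normalized reads. Some glucocorticoid receptor targets fell as well, with Fkbp5, a co-chaperone of the receptor, at 6312 ± 499 at 0 h and 3213 ± 92.8 at 4 h (1.96-fold lower), and Dusp1, a phosphatase of MAP kinases, and Per1 2.47-fold and 2.17-fold lower. Endoplasmic reticulum chaperones rose: Sdf2l1 was 3.77-fold higher (log2 1.92 ± 0.15, adjusted p = 2.34e-06), Herpud1, a factor of the degradation of misfolded proteins, 3.53-fold, Dnajb9 3.12-fold and Hspa5, the main chaperone of that compartment, 2.43-fold, from 39677 ± 4331 to 96952 ± 19068.

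Of 20 immediate early genes 17 fell and 3 did not pass (18 adjusted over the list alone), with a median log2 change of -1.08 (adjusted p = 3.97e-17, or 0.0166 with an estimated correlation). All 16 endoplasmic reticulum chaperones rose (16 adjusted over the list alone, median 0.66, adjusted p = 7.92e-17, or 0.117 with an estimated correlation). Of 21 glucocorticoid receptor targets 12 fell, 2 rose and 7 did not pass (14 fell and 3 rose adjusted over the list alone, adjusted p = 3.72e-06, or 0.0959 with an estimated correlation). In the ATF4 amino acid response list 10 of 16 rose, 1 fell and 5 did not pass (12 and 1 adjusted over the list alone, adjusted p = 1.02e-05, or 0.18 with an estimated correlation). Ddit3, a stress transcription factor, was 3.02-fold and Chac1 3.09-fold higher. Of the E-box or D-box clock genes 7 of 14 fell and 7 did not pass (8 adjusted over the list alone, adjusted p = 0.00036, or 0.187 with an estimated correlation). Nr1d2 was 2.47-fold and Nr1d1 2.11-fold lower, while Cry1 and Cry2, of the other clock lists, were 2.01-fold and 1.62-fold higher. Hypoxia and glycolysis genes had 10 higher, 1 lower and 12 not passing of 23 (10 and 2 adjusted over the list alone, adjusted p = 0.00155, or 0.187 with an estimated correlation). Pfkp, a phosphofructokinase, was 1.64-fold higher. In the mitosis (G2/M) list 10 of 25 rose, 1 fell and 14 did not pass (12 and 3 adjusted over the list alone, adjusted p = 0.00198, or 0.696 with an estimated correlation). Aurka, a spindle kinase, was 1.44-fold higher.

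Of 22 cytosolic ribosomal proteins 1, Rplp1, fell and 21 did not pass (1 adjusted over the list alone, median -0.09, adjusted p = 0.0157, or 0.872 with an estimated correlation). That list's call was also lost with quantile normalization, without 0 h replicate 1 and without 4 h replicate 1 (adjusted p = 0.0892, 0.0599 and 0.651; alternatives from 0.000221 to 0.872). For ribosome biogenesis genes 2 of 19 rose (5 with equal totals, 2 adjusted over the list alone, adjusted p = 0.0732, and 0.0231 with a replicate block, 0.0423 with no filter on the mean, 0.0378 with quantile normalization and 0.0349 without 0 h replicate 1; alternatives from 0.0231 to 0.872). Extracellular matrix genes went both ways, with 3 higher, such as Timp1, a metalloproteinase inhibitor (1.62-fold), 4 lower and 14 not passing of 21 (4 and 4 adjusted over the list alone, adjusted p = 0.756). Gbp2, an interferon-induced GTPase, was 2.76-fold lower and Ifit2 1.52-fold higher. Their list had 2 higher, 5 lower and 6 not passing of 13 (2 and 5 adjusted over the list alone, adjusted p = 0.246). Of 18 sterol synthesis genes 3 fell (3 adjusted over the list alone, adjusted p = 0.229). That list passed without 0 h replicate 2 and without 4 h replicate 2 (adjusted p = 0.00597 and 0.0479; alternatives from 0.00597 to 0.931). By camera, 8 of 24 lists passed and 16 did not (adjusted p from 0.0732 to 0.946), 1 of them with an estimated correlation. By fry, 7 lists passed.

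The largest rises by the naming rule among genes in none of the lists were those of Runx1t1, a transcriptional corepressor (3.36-fold), Adam12, a membrane metalloproteinase (3.2-fold), and Kcnj2 (2.81-fold). The largest falls there were those of Adamts1, a secreted metalloproteinase (5.56-fold), Cdh18, a cadherin (5.23-fold), and Arc (4.34-fold). The lists do not hold every gene of their kind, so a gene in none of them, such as Arc, can still belong to such a group. Errfi1, an inhibitor of the EGF receptor and a member of the glucocorticoid receptor target list, was 4.65-fold lower. Markers of other cell types were mostly low, and few were tested. Krt18, an epithelial keratin, was 1.85-fold higher, from 40.2 ± 0.58 to 75.6 ± 6.82, and Krt8 did not pass (adjusted p = 0.824). The call of Krt18 was lost without 0 h replicate 2 and without 4 h replicate 1 (adjusted p = 0.0942 and 0.102; alternatives from 0.0029 to 0.102). Of 5 tested neural markers 2 rose, Tubb3 and Nes, the progenitor filament nestin (1.59-fold and 1.57-fold; list median 0.66, adjusted p = 0.489). The call of Nes was lost without the filter on the mean, without the variance trend and without 0 h replicate 2, 4 h replicate 1 or 4 h replicate 2 (adjusted p = 0.05003, 0.0622, 0.346, 0.185 and 0.0540; alternatives from 4.84e-07 to 0.346). Of 5 leukocyte markers 1, Lyz2, was 2.14-fold lower (list adjusted p = 0.775), a call lost with quantile normalization, with edgeR, and without 0 h replicate 1, 0 h replicate 2 or 4 h replicate 1 (adjusted p = 0.0658, 0.0617, 0.0640, 0.170 and 0.208; alternatives from 0.00753 to 0.208). By DESeq2 0 of the 5 leukocyte markers passed. Over all genes, 1361 were higher and 1303 lower (51.1% higher), 71 and 109 of them by at least 2-fold. The count of 2664 was 4662 with a replicate block, 971 without 0 h replicate 2 and 1459 without 4 h replicate 1, and the share of higher genes was 61.4% with the libraries rescaled to the same total.

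The levels at 24 h were compared with those at 0 h, a day apart. Because 0 h was the end of the pulse, an equal phase of the clock at both times is not given and was not tested. Egr2, a zinc finger transcription factor, was 19.7-fold lower at 24 h (log2 -4.30 ± 0.13, adjusted p = 2.27e-11), Sphk1, a sphingosine kinase, 16-fold lower and Nppb, which encodes the natriuretic peptide B, 12.9-fold lower. The semaphorins Sema4f and Sema7a (14.2-fold and 11-fold), the stress factor Atf3 (9.63-fold) and the growth factor Hbegf (9.39-fold) were also among the lowest by the naming rule. Highest were Kcnj2 (11.6-fold, log2 3.53 ± 0.16, adjusted p = 1.65e-09), Txnip, an inhibitor of thioredoxin and of glucose uptake (5.75-fold), Rnf122 (4.97-fold), Ppp1r3c, a glycogen-targeting phosphatase subunit (4.9-fold), Fign (4.22-fold), Atoh8 (4.2-fold), the cytokine Il15 (3.84-fold) and Pappa2, a protease of IGF-binding proteins (3.71-fold). The call of Ppp1r3c was lost without 24 h replicate 2 (adjusted p = 0.0575; alternatives from 4.29e-06 to 0.0575).

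Dividing-cell transcripts were higher. All 25 mitosis (G2/M) genes rose (25 adjusted over the list alone, median log2 0.64, adjusted p = 6.12e-19, or 0.0542 with an estimated correlation). Cenpf, a kinetochore protein, was 2.14-fold and Kif20a, a mitotic kinesin, 1.78-fold higher. Of 25 DNA replication (G1/S) genes 23 rose and 2 did not pass (25 adjusted over the list alone, median 0.37, adjusted p = 5.75e-11, or 0.113 with an estimated correlation). Mcm5, part of the replicative helicase, went from 4249 ± 114 to 5839 ± 446. Of 20 immediate early genes 19 fell and 1 did not pass (19 adjusted over the list alone, median -1.49, adjusted p = 6.48e-17, or 0.0184 with an estimated correlation). With the replicate block as well as the estimated correlation the adjusted p was 0.0550 (alternatives from 1.85e-43 to 0.0550). SRF and MRTF cytoskeletal targets had 19 of 21 lower and 2 not passing (19 adjusted over the list alone, median -0.95, adjusted p = 4.43e-15, or 0.0542 with an estimated correlation). Ctgf and Cyr61, secreted matricellular proteins, were 7.12-fold and 4.25-fold lower and Vcl, the focal adhesion protein vinculin, 2.21-fold lower. In the extracellular matrix list 17 of 21 fell and 4 did not pass (17 adjusted over the list alone, median -0.55, adjusted p = 9.94e-09, or 0.104 with an estimated correlation). With equal totals 10 of them fell (median -0.34), and with quantile normalization 7 fell and 2 rose (median -0.24). Timp3 was 4.43-fold and Tnc, tenascin C, 2.73-fold lower. Glucocorticoid receptor targets had 13 lower, 3 higher and 5 not passing (14 and 3 adjusted over the list alone, adjusted p = 0.000131, or 0.104 with an estimated correlation). Fkbp5 was 2.64-fold and the metallothionein Mt2 4.89-fold lower.

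Sterol synthesis genes fell in 10 of 18 cases, with 1 higher and 7 not passing (11 and 1 adjusted over the list alone, adjusted p = 0.000131, or 0.217 with an estimated correlation). Of 23 hypoxia and glycolysis genes 10 were lower, led by Vegfa, the endothelial growth factor (6.09-fold), and Adm, adrenomedullin (3.08-fold), and 13 did not pass (10 lower and 1 higher adjusted over the list alone, adjusted p = 0.00087, or 0.128 with an estimated correlation). With the libraries rescaled to the same total 8 of them were higher and 8 lower, and the list's call was lost with quantile normalization (adjusted p = 0.0730; alternatives from 1.32e-05 to 0.249). Endoplasmic reticulum chaperones had 7 lower and 9 not passing of 16 (7 adjusted over the list alone, adjusted p = 0.0145, or 0.613 with an estimated correlation), against 3 lower and 3 higher with equal totals. Hspa5 was 1.47-fold lower. That list's call was lost with quantile normalization, with DESeq2, without 0 h replicate 1 and without 24 h replicate 1 (adjusted p = 0.253, 0.0519, 0.0827 and 0.0939; alternatives from 0.00219 to 0.613). Interferon-stimulated genes had 4 higher and 9 not passing of 13 (7 higher with equal totals, 4 adjusted over the list alone, adjusted p = 0.0444, or 0.392 with an estimated correlation), and Ifit2 was 2.91-fold higher. That call was lost with equal totals, with quantile normalization, without the variance trend, without 0 h replicate 1 and without 24 h replicate 2 (adjusted p = 0.279, 0.178, 0.0535, 0.0954 and 0.140; alternatives from 0.0215 to 0.392). Of 17 NF-kB and cytokine genes 8 fell, 2 rose and 7 did not pass (9 and 3 adjusted over the list alone), and with equal totals 6 fell and 6 rose. Ptgs2, the inducible cyclooxygenase, was 7.61-fold lower. That list had an adjusted p of 0.051, of 0.0240 with a replicate block, 0.00955 with equal totals, 0.0380 with no filter on the mean and 0.0472 with edgeR, and it passed without 4 h, 8 h or 28 h replicate 1 or 2 and without 24 h replicate 2 (adjusted p from 0.0349 to 0.0467; all alternatives from 0.00955 to 0.324).

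Of the 14 clock genes driven through E-boxes or D-boxes, 2 were higher, 4 lower and 8 did not pass (2 and 4 adjusted over the list alone). For the list the adjusted p was 0.349, or 0.00594 by fry. With equal totals 5 were higher and 4 lower. Hlf was 2.93-fold higher and Bhlhe40, Nr1d1 and Per1 4.6-fold, 1.64-fold and 1.57-fold lower. Of 22 cytosolic ribosomal proteins 0 passed with the deposited scaling by limma (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, 0 by edgeR and 0 by DESeq2). For the list the adjusted p was 0.95. With equal totals 17 of them rose and with quantile normalization 20 (adjusted p = 1.88e-06 for the list; alternatives from 1.88e-06 to 0.992). Heat shock proteins had 4 lower and 8 not passing of 12 (4 adjusted over the list alone, adjusted p = 0.26), but 6 higher and 3 lower with equal totals and 5 higher and 2 lower with quantile normalization. That list passed without 24 h replicate 2 (adjusted p = 0.0463; alternatives from 0.0463 to 0.821). Ribosome biogenesis genes had 3 higher, 5 lower and 11 not passing of 19 (adjusted p = 0.944), but 11 higher with equal totals. ATF4 targets had 3 higher, 5 lower and 8 not passing of 16 (adjusted p = 0.781), but 5 higher and 1 lower with equal totals. Of 4 tested replication-dependent histones 2 were lower (0 with equal totals, 1 with quantile normalization and 1 by DESeq2, adjusted p = 0.416). How the reads of near-identical histone copies were counted was not tested.

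Markers of other cell types moved beside these groups. Krt8, an epithelial keratin, was 7.86-fold lower at 24 h, from 935 ± 204 to 118 ± 27.3, Krt18 was 2.35-fold lower, and Krt14 did not pass, which made 2 of 3 tested epithelial markers lower (median -1.23, adjusted p = 0.0269, or 0.293 with an estimated correlation). Without the filter on the mean that list did not pass (adjusted p = 0.140; alternatives from 0.00453 to 0.334). The other 7 epithelial markers had means under 10 normalized reads. Acta1, the skeletal muscle actin, was 4.4-fold lower, with reads that other actin genes can share, and Des and Tnnt3 did not pass. The median of these 3 muscle markers was 0.19 and their mean -0.55. The list had an adjusted p of 0.416, 0.0323 with DESeq2 and 2.96e-05 by fry (camera alternatives from 0.0323 to 0.862). Nes was 1.96-fold lower, 1 of 5 tested neural markers to pass (2 higher and 1 lower with equal totals, 2 lower with quantile normalization, adjusted p = 0.944, median 0.20, mean -0.05). Leukocyte markers had 0 of 5 passing by limma (0 adjusted over the list alone, 2 at an unadjusted p under 0.05, 0 by edgeR and 0 by DESeq2, adjusted p = 0.95), and endothelial markers 1 lower of 4 (0 with equal totals and 0 by DESeq2, adjusted p = 0.416). With a replicate block Cd68 and Csf1r of the leukocyte list passed (adjusted p = 0.0019 and 0.034), with equal totals Cd68 did (0.0153), and with quantile normalization and without 24 h replicate 1 Csf1r did (adjusted p = 0.0308 and 0.0257, alternatives of both from 0.0019 to 0.557). Of the adipocyte markers Lpl and Fabp4 were tested and did not pass (adjusted p = 0.424 and 0.749). With a replicate block Lpl passed (adjusted p = 0.044, alternatives from 0.044 to 0.859). In all, 2309 genes were higher and 2302 lower (50.1% higher), 164 and 401 by at least 2-fold, and the share of higher genes was 81.0% with equal totals. By camera 11 of 24 lists passed and 13 did not (adjusted p from 0.0510 to 0.991), 1 with an estimated correlation, and 16 passed by fry.

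**Figure D3:**
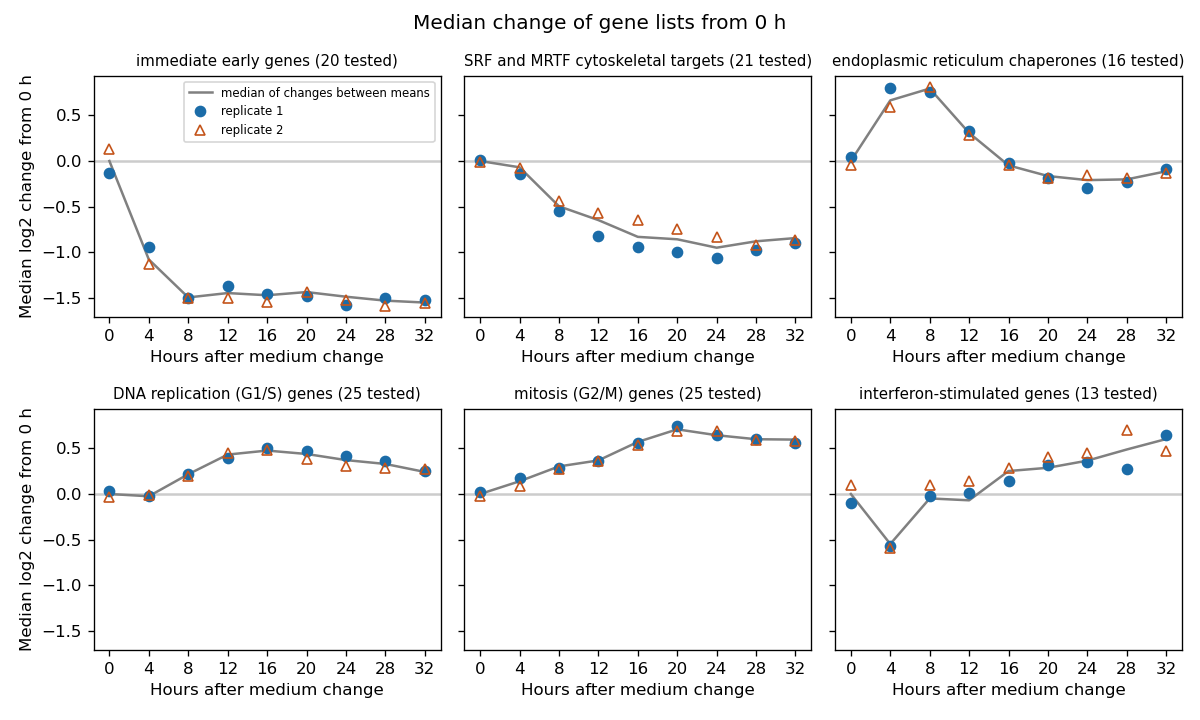
Median log2 change from 0 h (vertical axis) of 6 gene lists against hours after the medium change (horizontal axis), with a point for the median of each replicate and a line for the median of the changes between the means of both libraries. The line of the immediate early list is at -1.08 at 4 h and -1.49 at 24 h, the SRF and MRTF list at -0.95 at 24 h, the mitosis (G2/M) list at 0.64 at 24 h, and the endoplasmic reticulum chaperones at 0.66 at 4 h and -0.21 at 24 h, near 0 there when libraries are rescaled to the same total.

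A day separated 28 h from 4 h as well, without the libraries of 0 h. Sema7a, a membrane-anchored semaphorin, was 20.6-fold lower at 28 h (log2 -4.36 ± 0.30, adjusted p = 1.09e-07), from 11416 ± 1261 to 557 ± 106. Nppb (13.7-fold), Serpinb2, a plasminogen activator inhibitor (13.2-fold), Sema4f (11.6-fold), the growth factor Fgf2 (7.49-fold), Ctsw, a cathepsin (7.02-fold), and Krt8 (6.91-fold) were also among the lowest. Highest were Hdac9, a histone deacetylase (5.16-fold, log2 2.37 ± 0.53, adjusted p = 0.0025), Pappa2 (4.84-fold), Angpt1, angiopoietin 1 (4.83-fold), Atoh8 (4.36-fold), Tspan33 (4.12-fold), Kcnj2 (4.12-fold), Akr1c14 (4.05-fold) and Abcd2, a peroxisomal transporter (3.91-fold).

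All 16 endoplasmic reticulum chaperones were lower at 28 h (16 adjusted over the list alone, median log2 -1.07, adjusted p = 4.23e-13, or 0.152 with an estimated correlation). Herpud1 was 3.69-fold and Hspa5 3.14-fold lower. ATF4 targets had 10 lower and 6 not passing of 16 (10 adjusted over the list alone, adjusted p = 0.000279, or 0.173 with an estimated correlation), and Atf4 itself was 1.52-fold lower. The cytoskeletal SRF and MRTF list had 19 lower and 2 not passing of 21 (19 adjusted over the list alone, median -0.81, adjusted p = 4.23e-13, or 0.116 with an estimated correlation), and Ankrd1 was 4.18-fold lower. The matrix list had 10 lower and 11 not passing (11 adjusted over the list alone, adjusted p = 3.33e-06, or 0.159 with an estimated correlation), against 9 lower and 1 higher with equal totals and 7 lower and 3 higher with quantile normalization. In it Timp1 was 4.02-fold lower. Immediate early genes had 13 lower, 1 higher and 6 not passing of 20 (13 and 1 adjusted over the list alone, median -0.54, adjusted p = 0.000113, or 0.159 with an estimated correlation), and Maff was 3.51-fold lower. Hypoxia and glycolysis genes had 14 lower and 9 not passing of 23 (15 adjusted over the list alone, adjusted p = 4.17e-08, or 0.0896 with an estimated correlation). Ndrg1 was 3.97-fold and Vegfa 4.81-fold lower. Of 25 mitosis (G2/M) genes 22 rose and 3 did not pass (22 adjusted over the list alone, median 0.45, adjusted p = 1.2e-12, or 0.13 with an estimated correlation). Of 25 DNA replication (G1/S) genes 20 rose and 5 did not pass (21 adjusted over the list alone, median 0.37, adjusted p = 3.65e-08, or 0.159 with an estimated correlation). Ccnb2, cyclin B2, was 1.93-fold and Pola1, a DNA polymerase subunit, 1.47-fold higher.

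Interferon-stimulated genes rose in 9 of 13 cases and 4 did not pass (9 adjusted over the list alone, median 0.95, adjusted p = 0.000682, or 0.159 with an estimated correlation). Gbp2 was 3.27-fold and Ddx58, the RNA sensor RIG-I, 2.46-fold higher. Cytosolic ribosomal proteins, whose pseudogenes can share reads, had 8 higher and 14 not passing of 22 (4 adjusted over the list alone, adjusted p = 0.00167, or 0.598 with an estimated correlation), and 21 higher with equal totals and 22 with quantile normalization. Their call was lost without 4 h replicate 1 (adjusted p = 0.0683; alternatives from 3.29e-10 to 0.598). Ribosome biogenesis genes had 10 lower and 9 not passing of 19 (10 adjusted over the list alone, adjusted p = 0.000867, or 0.596 with an estimated correlation), against 3 higher and 3 lower with equal totals. Gnl3, nucleostemin, was 1.31-fold lower. Quantile normalization ended the list's call (adjusted p = 0.150; alternatives from 0.000112 to 0.596). Of 18 sterol synthesis genes 8 fell and 2 rose (9 and 3 adjusted over the list alone, adjusted p = 0.0608, 0.0467 with a replicate block and 0.0267 with no filter on the mean; alternatives from 0.0144 to 0.598), against 4 lower and 6 higher with equal totals. That list also passed without 4 h replicate 1, 28 h replicate 2, 0 h replicate 1 and 0 h replicate 2 in turn (adjusted p = 0.0144, 0.0178, 0.0437 and 0.0437). Heat shock proteins had 5 lower of 12 (5 adjusted over the list alone, adjusted p = 0.0878), but 2 higher and 2 lower with equal totals and 2 higher with quantile normalization. That list passed with no filter on the mean (adjusted p = 0.0469; alternatives from 0.0469 to 0.656). Glucocorticoid receptor targets had 6 higher, 7 lower and 8 not passing of 21 (8 and 6 with equal totals, 7 and 5 with quantile normalization, 6 and 7 adjusted over the list alone, adjusted p = 0.699; alternatives from 0.308 to 0.938). NF-kB and cytokine genes had 5 higher, 6 lower and 6 not passing of 17 (adjusted p = 0.465).

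Clock genes driven through E-boxes or D-boxes went both ways, with 4 higher and 3 lower of 14 (6 and 2 with equal totals, 5 and 4 adjusted over the list alone, adjusted p = 0.87, median 0.10, mean -0.01). Bhlhe40 was 3.51-fold and Ciart 2.5-fold lower, and Hlf 2.93-fold higher. Arntl was 1.24-fold higher, a call lost without 4 h replicate 1 and without 28 h replicate 1 (adjusted p = 0.134 and 0.074; alternatives from 0.000303 to 0.134). Krt8 and Krt18 were lower (5.72-fold for Krt18), 2 of 3 epithelial markers (median -2.52, adjusted p = 0.0178, or 0.269 with an estimated correlation). Acta1 was 6.73-fold lower, in a muscle list with an adjusted p of 0.269, 0.00118 with DESeq2 and 2.09e-06 by fry (camera alternatives from 0.00118 to 0.477). Neural markers had 2 higher and 2 lower of 5, with Nes 3.29-fold lower (list adjusted p = 0.527, or 0.00453 by fry). Of 5 leukocyte markers 1, Lyz2, was 3.53-fold higher (list adjusted p = 0.682, or 0.0411 by fry). Of 2 adipocyte markers 1, Lpl, was 2.19-fold higher, a call lost without 4 h replicate 1 and without 28 h replicate 2 (adjusted p = 0.0605 and 0.0705; alternatives from 2.00e-07 to 0.0705). Over all genes 2557 were higher and 2569 lower (49.9% higher), 249 and 407 by at least 2-fold. The count of 5126 was 3409 without 28 h replicate 2, and the share of higher genes was 77.8% with equal totals, which moved the median of all genes by 0.19 log2. By camera 12 of 24 lists passed and 12 did not (adjusted p from 0.0608 to 0.909), 0 of them with an estimated correlation, and 18 passed by fry.

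Between 8 h and 32 h, the last pair of times a day apart, Gdpd2, a phosphodiesterase (8.18-fold, log2 3.03 ± 0.55, adjusted p = 0.00135), and Pappa2 (7.96-fold, log2 2.99 ± 0.26, adjusted p = 6.48e-06) were highest at 32 h, before Bmf, a pro-apoptotic BCL2 family member (4.2-fold), and Apol6 (3.97-fold). Dpep1 (4.73-fold), Scara5 (3.77-fold), Ppp1r3c (3.59-fold) and Hdac9 (3.36-fold) were also among the 8 highest, but none of these 4 passed without 8 h replicate 1 (adjusted p = 0.104, 0.108, 0.125 and 0.23) or without 32 h replicate 2 (0.0822, 0.165, 0.161 and 0.167; alternatives of the 4 from 2.68e-08 to 0.23). Serpinb2 was 11.9-fold lower (log2 -3.58 ± 0.42, adjusted p = 5.52e-05), Sema7a 10.5-fold, Ctsw 6.36-fold, Lrrc15 5.31-fold, Sema4f 4.83-fold, Acta1 4.41-fold and Tnnt2, cardiac troponin T, 4.09-fold. Mmp10, a stromelysin, was 6.17-fold lower and did not pass without 8 h replicate 1 or without 32 h replicate 2 (adjusted p = 0.0915 and 0.176; alternatives from 2.39e-06 to 0.176).

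Endoplasmic reticulum chaperones fell in 15 of 16 cases with 1 not passing (16 adjusted over the list alone, median log2 -0.88, adjusted p = 2.49e-16, or 0.23 with an estimated correlation). Hyou1 was 2.52-fold and Hsp90b1 2.04-fold lower. Cytosolic ribosomal proteins rose in 19 of 22 cases with 3 not passing (20 adjusted over the list alone, median 0.30, adjusted p = 4.8e-10, or 0.285 with an estimated correlation), and Rplp1 was 1.35-fold higher. Of 19 ribosome biogenesis genes 12 fell and 7 did not pass (15 adjusted over the list alone, median -0.28, adjusted p = 2.4e-06, or 0.379 with an estimated correlation), and Dkc1, the dyskerin of snoRNA particles, was 1.39-fold lower. Mitosis (G2/M) genes rose in 20 of 25 cases with 5 not passing (21 adjusted over the list alone, median 0.29, adjusted p = 1.07e-10, or 0.23 with an estimated correlation), and Ccnb2 was 1.72-fold higher. DNA replication (G1/S) genes had 5 higher and 20 not passing of 25 (5 adjusted over the list alone, median 0.02; adjusted p = 0.518). Interferon-stimulated genes had 9 higher and 4 not passing of 13 (9 adjusted over the list alone, median 0.64, adjusted p = 0.000116, or 0.23 with an estimated correlation), and Gbp2 was 2.56-fold higher. Sterol synthesis genes had 9 higher, 1 lower and 8 not passing of 18 (14 and 0 with equal totals, 11 and 1 adjusted over the list alone, adjusted p = 0.000209, or 0.285 with an estimated correlation), and Fdft1, squalene synthase, was 1.49-fold higher.

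The cytoskeletal SRF and MRTF list had 13 lower, 1 higher and 7 not passing of 21 (14 and 1 adjusted over the list alone, median -0.42, adjusted p = 3.55e-07, or 0.236 with an estimated correlation), and Ctgf was 3.58-fold lower. The matrix list had 9 lower and 12 not passing of 21 (11 adjusted over the list alone, adjusted p = 1.88e-05, or 0.236 with an estimated correlation), and Fbn1, fibrillin, was 1.84-fold lower. Hypoxia and glycolysis genes had 8 lower and 15 not passing of 23 (9 adjusted over the list alone, adjusted p = 0.00271, or 0.236 with an estimated correlation), and P4ha2 was 1.83-fold lower. Glucocorticoid receptor targets had 8 higher, 5 lower and 8 not passing of 21 (10 and 5 adjusted over the list alone, adjusted p = 0.0479, or 0.379 with an estimated correlation). Cebpd was 2.5-fold and Ddit4, an inhibitor of mTOR, 1.98-fold higher. That list's call was lost without 8 h replicate 1, without 32 h replicate 2 and without a library of 20 h or 24 h (adjusted p = 0.108, 0.135 and from 0.0518 to 0.0533). It was also lost with equal totals, quantile normalization and no variance trend (adjusted p = 0.109, 0.0522 and 0.0648; all alternatives from 0.0104 to 0.379). The ATF4 list had 5 lower, 1 higher and 10 not passing of 16 (6 and 1 adjusted over the list alone, adjusted p = 0.0454, or 0.478 with an estimated correlation), and Asns, asparagine synthetase, was 1.3-fold lower. Its call was lost without 8 h replicate 2, without 32 h replicate 2 and without a library of 20 h or 24 h (adjusted p = 0.0685, 0.134 and from 0.0503 to 0.0533). It was also lost with quantile normalization and no variance trend (adjusted p = 0.146 and 0.0593; all alternatives from 0.0113 to 0.478). Immediate early genes had 3 higher, 5 lower and 12 not passing of 20 (4 and 5 adjusted over the list alone), with a median of -0.03, a mean of 0.06 and camera's direction down (adjusted p = 0.671). Btg2 was 2.04-fold higher and Jun 1.44-fold lower.

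Of 14 clock genes driven through E-boxes or D-boxes 2 were higher and 1 lower at 32 h (1 and 1 adjusted over the list alone, adjusted p = 0.172), and 6 were higher and 1 lower with equal totals. With the deposited scaling these were, among others, Per1 1.37-fold higher and Bhlhe40 1.7-fold lower. Nfil3, a repressor of the clock's output, was 1.64-fold higher. NF-kB and cytokine genes had 4 higher and 5 lower of 17 (4 and 5 adjusted over the list alone, adjusted p = 0.87), and the chemokine Cxcl12 was 1.86-fold lower. Heat shock proteins had 3 lower of 12 (3 adjusted over the list alone, adjusted p = 0.134), 1 with equal totals and 0 with quantile normalization. Krt8 and Krt18 were 3.15-fold and 1.9-fold lower, 2 of 3 epithelial markers (2 adjusted over the list alone, adjusted p = 0.085, 0.0293 without 8 h replicate 2, 0.0432 with equal totals and 0.0281 with DESeq2; alternatives from 0.0281 to 0.448). Krt18 did not pass without 8 h replicate 1 or without 32 h replicate 2 (adjusted p = 0.0831 and 0.0634; alternatives from 0.00215 to 0.0831). By DESeq2 1 of the 3 epithelial markers passed. Muscle markers split, with Acta1 lower and Des, desmin, 2.72-fold higher. The muscle list had an adjusted p of 0.97, 0.0281 downward with DESeq2 and 0.00375 by fry (camera alternatives from 0.0281 to 0.999). Of the neural markers Tubb3 was 2.48-fold lower and Mtap2 1.92-fold higher among 1 higher and 2 lower of 5 (list adjusted p = 0.771, or 0.0435 by fry). Lyz2, 1 of 5 leukocyte markers, and Lpl, 1 of 2 adipocyte markers, were 2.12-fold and 2.0-fold higher (leukocyte list adjusted p = 0.484, or 0.0352 by fry). Neither passed without 8 h replicate 1 (adjusted p = 0.152 and 0.191) or without 32 h replicate 2 (0.133 and 0.141), and Lyz2 also not with quantile normalization or without 32 h replicate 1 (0.0629 and 0.0807; alternatives of both from 2.24e-06 to 0.191). By DESeq2 0 of the 5 leukocyte markers passed. By camera 11 of 24 lists passed and 13 did not (adjusted p from 0.0850 to 0.970), 0 with an estimated correlation, and 16 passed by fry, the split muscle list among them. Over all genes 1669 were higher and 1753 lower (48.8% higher), 165 and 142 by at least 2-fold. The count of 3422 was 5241 with a replicate block, 1782 without 8 h replicate 1 and 1554 without 32 h replicate 2, and the share of higher genes was 68.0% with equal totals.

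A change over the culture time was measured as the slope of time beside the 24 h cosine and sine. The slope does not show that a change was steady, because an early change that then levels off also gives one. The folds are those of the fitted line and can differ from those of measured levels. Sema7a fell most steeply, at -0.15 ± 0.0076 log2 per hour, which is a fitted 30.6-fold over 32 h (adjusted p = 1.01e-10), while its measured level was 11416 ± 1261 at 4 h and 486 ± 63.9 at 32 h. Sema4f, Serpinb2 and Nppb were lower by 19.8-fold, 16.8-fold and 14.8-fold over the same span. Kcnj2 rose most, a fitted 8.91-fold over 32 h, followed by Pappa2 (8.65-fold), Txnip (5.52-fold), Gdpd2 (5.48-fold) and Ppp1r3c (5.48-fold). In all 6880 of 12393 genes had such a slope, 3492 upward and 3388 downward (50.8% upward). The count was 4462 without 0 h and 4 h, and the upward share was 78.4% with the libraries rescaled to the same total.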

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

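Chosen after the data were seen were the decaying term, leaving out 0 h, 4 h and 8 h, the block with 0 h and 4 h left out, the block with an estimated correlation, and the drift without 0 h and 4 h. Apart from left-out libraries and replicates, named genes kept their direction and side of the threshold in 6931 comparisons with an alternative, passed newly in 245, no longer passed in 88 and reversed in 7. For lists these were 1634, 51, 94 and 1. With libraries left out genes held in 10005, passed newly in 39 and no longer passed in 268, and lists in 2167, 20 and 21.

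The number of genes with a 24 h rhythm, 46, was 26 with no filter on the mean, 19 with libraries rescaled to the same total, 74 with a replicate block, 556 with DESeq2, 77 without 0 h, 142 without 0 h and 4 h and 1099 without 0 h, 4 h and 8 h. It was 2108 with a linear term in time, 289 with a decaying transient term and 381 with a replicate block and without 0 h and 4 h. Periods of 20 h, 22 h, 26 h and 28 h gave 8, 15, 344 and 1432. A fitted peak-to-trough fold of at least 1.5 gave 23 and a threshold of 0.01 gave 17. The times left without 0 h, 4 h and 8 h span less than 24 h, so a drift can be fitted there as part of a cycle. With a replicate block 4662 genes passed at 4 h against 0 h and 5241 at 32 h against 8 h. With at least 1.5-fold 689 passed at 4 h and 1638 at 24 h against 0 h, 1802 at 28 h against 4 h and 893 at 32 h against 8 h. The drift count was 4462 without 0 h and 4 h. Leaving out libraries or replicates gave ranges of 1 to 48 for the rhythm, 971 to 2719 for 4 h and 2571 to 4331 for 8 h against 0 h, 3409 to 5159 for 28 h against 4 h and 1554 to 3508 for 32 h against 8 h.

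Reversed values were those of Hspa4 at 24 h against 0 h with equal totals (log2 0.0066) and quantile normalization (0.074), of Bag3 with equal totals (0.017) and Hsp90aa1 with quantile normalization (0.17) at 28 h against 4 h, and of the skeletal muscle markers at 32 h against 8 h with DESeq2 (adjusted p = 0.0281, alternatives from 0.0281 to 0.999). The fitted peaks of Hlf, Krt8 and Acta1 lay more than 6 h away without 0 h, 4 h and 8 h (peak-to-trough log2 0.91, 0.97 and 1.38). The block ended no call of a named gene or list with the preset correlation, and beyond the values given beside the results it changed no other call printed here. A stricter threshold or minimum fold lowers a count by construction, and leaving out libraries leaves fewer samples; the other causes were not tested. At these depths genes with a mean under 10 normalized reads, among them most markers of other cell types, were left out of the tests, so no statement is made on them.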

Other observations

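The tests of the drift of replicate 2, of a later harvest of replicate 2, of the totals at 0 h and 4 h and of orders within each replicate were chosen after the results they measure had been seen. Cell cycle genes reached their highest medians one after the other. The DNA replication (G1/S) list had a median log2 change from 0 h of -0.02 at 4 h, 0.22 at 8 h, 0.43 at 12 h, 0.48 at 16 h and 0.24 at 32 h. The mitosis (G2/M) list had 0.30 at 8 h, 0.37 at 12 h, 0.57 at 16 h, 0.71 at 20 h and 0.60 at 32 h. With equal totals these medians lie higher by the shift of that scaling, from 0.14 at 8 h to 0.22 at 32 h, which turns only the sign at 4 h of the first list. These are medians of 25 genes each, without a test of the difference in timing.

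Stress and lipid groups had courses of their own. Endoplasmic reticulum chaperones had medians of 0.66 at 4 h, 0.79 at 8 h, 0.31 at 12 h, -0.05 at 16 h and -0.11 at 32 h, the negative ones within the shift of the scaling. Sterol synthesis genes had -0.01 at 4 h, -0.43 at 8 h, -0.59 at 12 h, -0.22 at 28 h and -0.03 at 32 h, of which those at 4 h, 28 h and 32 h lie within that shift. Interferon-stimulated genes had -0.55 at 4 h, -0.05 at 8 h (positive with equal totals), 0.25 at 16 h and 0.60 at 32 h. Glucocorticoid receptor targets had -0.42 at 4 h, -0.92 at 8 h, -0.87 at 12 h, -0.57 at 24 h and -0.67 at 32 h.

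Chance was examined by giving the libraries other time labels. Of 100 orders of the 18 libraries 1, the real one, gave 6439 or more genes that differed among the times (highest other 517), and with the times reordered within each replicate it was again 1 of 100 (highest other 2920), so chance can be excluded for that count on both tests. For the rhythm 3 of the 100 orders of all libraries and 2 of the 100 within replicates gave 46 or more genes (highest other 1748 and 1280), but both part the libraries of a time. With the libraries of a time kept together, 28 of 100 orders of the 9 times gave 46 or more rhythmic genes and the highest other 5350. Such orders keep the differences among times that 6439 genes showed. Counts many times the real one can come from these differences, whose share was not tested. Chance cannot be excluded for the count of 46.

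The rhythm count went from 46 to 2108 with a linear term in time, all 46 included. A cycle plus a line requires equal changes over the 3 day-long intervals, and these differed in 807 of the 2108 genes (38.28%), in 16 of the 46 (34.78%) and in 2241 of all 12393 (18.08%). Of the 2108 genes 46.02% peaked within 2 h of 1.84 h or 13.8 h (33.33% with no preferred hour). Beside a line, a decay with a constant of 6 h would be fitted with its peak or its opposite at these hours. Of the 46 genes, fitted without a line, 54.35% peaked within 2 h of the same hours. The hours of a decay in that fit were not worked out, so this share does not bear on a decay. The 38.28% and the 46.02% lie between those named in advance for a decaying response read as part of a cycle and for a cycle alone, so these cannot be told apart: the series covers little more than a cycle, and the early changes fall in its first hours. A biological rhythm of part of these genes may remain, as an untested hypothesis.

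At matched hours 4700 genes differed between the replicates, 2476 higher and 2224 lower in replicate 2, with a median size of 0.15 log2. Igf2, a growth factor, was 3.18-fold, and the matrix proteins Postn, Aspn and Prelp 3.03-fold, 2.90-fold and 2.41-fold higher in replicate 2, each at 9 of 9 times, and Mmp10 was 2.08-fold lower. Sequencing depth is argued against as the cause: with all libraries thinned to 25.4 M reads 4501 genes differed, 4313 of them shared. GC content and transcript length explained 4.354% of the variance over the 11115 genes (89.7% of those tested) with both values. That argues against them as the main cause, though noise in the difference also lowers this share. A later harvest of replicate 2 is argued against by the clock genes past the rhythm test. They peaked earlier in replicate 2 by a median of -0.08861 h, that is no earlier, against the 2.84 h that the drift would need. The SE over these 13 genes was 0.0597, but they are not independent replicates. The most that any of them peaked earlier was 0.385 h. A state further along the culture's drift stays open, with a correlation over genes of 0.2758 between the replicate difference and the drift (genes are not independent replicates). Of the lists that fell by 24 h, some were mostly higher in replicate 2 (SRF and MRTF 12 higher and 3 lower, matrix 11 and 3, glucocorticoid receptor targets 10 and 1), and the G1/S and mitosis lists, which rose, were mostly lower (1 and 8, 3 and 6), against that state. Other lists with more falls than rises by 24 h went with it or were near even (immediate early 2 and 4, endoplasmic reticulum chaperones 2 and 3, NF-kB 4 and 6, epithelial markers 0 and 1, sterol 5 and 3, hypoxia 7 and 5). Interferon-stimulated genes (5 and 0), cytosolic ribosomal proteins (16 and 0) and ribosome biogenesis genes (0 and 12) went with their changes from 8 h to 32 h. Open as well are separate cultures, for which the labels give no test.

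Normalized totals at 0 h and 4 h exceeded those from 12 h to 32 h by 13.49%. Without the 100 genes with the highest mean the totals of the other genes still differed by 8.581%, against a few genes as the whole cause. That percentage is 63.59% of the first. It is not a share of the extra reads, because the totals beneath the percentages differ. The 10 genes with the largest part made 28.94% of the excess, among them Itga5, Thbs1, Acta2 and Fn1, whose products link the cell to its matrix or form its cytoskeleton. Which of the scalings reflects the RNA per cell stays open, since no spike-in is described. No biological explanation of the totals was tested.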
